A study of Homo sapiens with 6 samples.

How the data were processed

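Total RNA of 6 samples of SK-N-BE(2) cells, 3 infected with a non-silencing control lentivirus and 3 with a BRG1 hairpin lentivirus, was hybridised to 1 single-colour Affymetrix array each, per the labels' protocols. The groups follow the lentivirus label of each sample, which reads shBRG1 where the titles spell shRG1. No transcript level of the target was used to check them, and the replicate numbers are those of the titles. The deposited values are log2 expression values per probe set, and per the submitters' processing notes RMA, oligo 1.27, limma 3.19 and R 3.1.0 were used. RMA corrects background, sets arrays to a common distribution and summarises probes, so a shift of all genes at once would not be seen, and changes of dim and very bright probe sets can be understated. The scale was taken as log2 from the range of the values, 1.19 to 13.8. Scanner files, detection calls, array batches and scan days were not used here, and the genome build behind the probe design is not given in the sources used here. The number of arrays, 3 per group, limits the precision, and the median standard error of a log2 change was 0.09.

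The table held 52299 probe sets. A platform annotation gave 15828 of them 1 gene symbol, 0 several and 36471 none, and all 15828 symbols were brought up to date through gene identifiers of the GRCh38.p14 gene table. Of several probe sets of a gene the one with the highest mean over the 6 arrays was kept, which left 14883 genes and set aside 945 probe sets. Probe sets with no symbol are unnamed here and entered only the count over every probe set. SMARCA4 is among the genes without a named probe set, so its planned comparison was not run. No filter on dim genes was applied, and all 6 columns of samples were mapped.

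Each gene was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend or robust options, two-sided), shBRG1 against NSC without covariates, and p-values were adjusted by Benjamini and Hochberg over all named genes with a threshold of 0.05. Changes are the mean of shBRG1 minus the mean of NSC on the log2 scale, with the moderated standard error. An exact permutation test of 3 against 3 cannot go below a two-sided p of 0.1, so single genes rest on the pooled spread of limma. The 18 gene lists comprised other SWI/SNF subunits, anti-apoptotic and survival factors, pro-apoptotic factors and caspases, p53 targets, PI3K/AKT/mTOR signalling, DNA replication and G1/S, G2/M and mitosis, MYC/MYCN targets, adrenergic identity, mesenchymal identity, neuronal differentiation, type I interferon response, stress response, cholesterol, extracellular matrix, hypoxia and glycolysis, Schwann and glial markers, and reference genes. They were written from textbook knowledge, and 339 of their 579 genes were measured. ERBB3 and PGK1 each stand in 2 lists. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry (statmod 1.5.0 installed). Each list was also counted by its members past the threshold over all genes and adjusted over the list alone.

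The text names the 10 genes that rose most and the 10 that fell most among those past the threshold whose 3 shBRG1 values lie outside the NSC range, leaving out uncharacterised loci and small RNA genes. It also names up to 4 members of each list with the smallest p, and BCL2, BCL2L1, MYC, CCND1, AKT1, IGF1R, CD44 and KIF18A with or without a change. Where 5 or fewer members of a list went one way, the remaining ones were named after their values were seen (BCL7A, RRM2B, DDIT4, TSC1, MET, MCM5, MCM7, GINS2, GINS3, FBL, LIN28B, TBX2, MAML2, CTH, NSDHL and SQLE), as was MCM6. The groups, tests, lists, naming rule and alternatives were fixed before the data were examined, except where the text says otherwise.

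Alternatives were centring each array on its median, cyclic loess between arrays, leaving out genes dimmer than the median gene, averaging the probe sets of a gene, eBayes with trend and robust options, array quality weights, the replicate number as a block, leaving out each array in turn, testing every probe set, an adjusted p of 0.01, and a fold of at least 2. The fit was tested on simulated data with 14883 genes and 3 arrays per group. It recovered 53 of 100 genes changed by 0.5 and 98 of 100 changed by 1 on the log2 scale. There were 6 unchanged genes among 157 calls, and 0 calls where nothing was changed. Only 200 genes were changed and errors were independent between genes, so these rates need not hold for the real arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.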

Results

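Gene expression was measured in SK-N-BE(2) cells, an established human neuroblastoma line known to carry amplified MYCN. The cells were infected with a lentivirus carrying a non-silencing control hairpin (NSC, n = 3) or a hairpin against BRG1 (shBRG1, n = 3). BRG1 is the ATPase of the SWI/SNF chromatin remodelling complex and is encoded by SMARCA4. RNA was taken 48 h after infection, and 200 ng of total RNA per sample went onto 1 Affymetrix array. Each of the 6 arrays gave log2 values for 52299 probe sets, with medians between 3.77 and 3.84, and 15828 probe sets carried a gene symbol, for 14883 genes. Arrays correlated more closely within a group (Pearson r across probe sets 0.9907 to 0.9925) than between groups (0.9860 to 0.9881). The first principal component held 54.8% of the variance and placed the 3 shBRG1 arrays at 15.4 to 18.1 and the 3 NSC arrays at -17.3 to -15.7. The transductions are described as triplicates, without saying whether the cultures were handled separately, so the p-values measure only the spread between these samples, which may be technical.

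The comparison asks which transcripts differ when cells carry the BRG1 hairpin, in a study concerned with cell viability, death and survival pathways. The depletion of the target itself was not analysed here, because no probe set used carried the symbol SMARCA4. The samples are therefore described by their labels alone. SMARCA2, MYCN, CDKN1A and PIK3CA were likewise not analysed here.

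The hairpin went with a broad change of the transcriptome, and among genes with a symbol more fell than rose by at least 2-fold. GCH1, the rate-limiting enzyme of tetrahydrobiopterin synthesis, was 4.64-fold lower (log2 change -2.21, SE 0.08, adjusted p = 7.5e-05), from 8.61 ± 0.03 in NSC to 6.39 ± 0.12 in shBRG1 (SD, n = 3). BCL2, the founding anti-apoptotic member of its family, was 3.17-fold lower (-1.67, SE 0.12, adjusted p = 3.0e-04), from 8.47 ± 0.10 to 6.81 ± 0.21. FN1, which encodes the matrix protein fibronectin, was 2.71-fold higher (1.44, SE 0.11, adjusted p = 4.1e-04), from 5.07 ± 0.08 to 6.51 ± 0.20. LINC00265, a long non-coding RNA that lies outside the naming rule and was picked after its value was seen, was 2.89-fold higher (1.53, SE 0.09), with a change of 0.97 when its probe sets were averaged (adjusted p = 6.0e-04).

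Among the 14883 genes tested with limma, 2525 (17.0%) passed an adjusted p of 0.05, 1455 of them higher and 1070 lower in shBRG1. A change of at least 2-fold was present in 33 of the higher and 70 of the lower genes. The median change was 0.42 among the higher calls and -0.46 among the lower ones, against 0.01 over all genes. The 3 shBRG1 values lay entirely outside the NSC range for 35.5% of genes, where chance gives 10%. By annotation, calls took in 2304 of 11916 protein-coding genes, 112 of 1397 long non-coding RNAs and 74 of 1072 microRNA genes. The split between higher and lower calls depended on scaling, with 57.6% higher in the deposited values and 47.7% (1212 higher, 1329 lower) after cyclic loess. The count fell to 1633, 1662 and 1604 without shBRG1 replicate 1, 2 or 3, and the higher genes to 939, 840 and 904, or to 900 without NSC replicate 2. The lower genes numbered 694 and 700 without shBRG1 replicate 1 or 3.

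The other genes with the largest falls under the naming rule included NES (nestin, an intermediate filament protein of neural progenitors, -1.65) and SCG2 (secretogranin II, a protein of neuroendocrine secretory granules, -1.65). MBNL3, an RNA-binding splicing regulator, fell by 1.80 on the log2 scale, and TWSG1, a modulator of BMP signalling, by 1.78. VAMP3, a SNARE protein of recycling vesicles, had a change of -1.77, and the depalmitoylating enzyme LYPLA1 one of -1.67. PM20D2 (-1.68) and HABP4 (-1.66) completed this set, in which folds ranged from 3.13 (SCG2) to 4.64 (GCH1). Rises were smaller. The tumour suppressor NF2, which encodes merlin, was 2.49-fold higher, MAP2K6, an activating kinase of p38, 2.38-fold, and the p53-inducible gene TP53INP1 2.37-fold. TP53INP1 was dim in NSC (3.89 ± 0.13, near the array medians), so the size of its fold rests on a value that may be background. PLPPR2 (2.61-fold), the transmembrane protein gene TMEFF2 (2.41-fold), TMCC1-DT (2.39-fold), KLHDC3 (2.33-fold), the protocadherin PCDH10 (2.32-fold) and ANKRD52 (2.30-fold) were also higher. All 20 of these genes had an adjusted p of 0.00112 or below, and they passed under every alternative run in which they were tested.

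**Figure D1:**
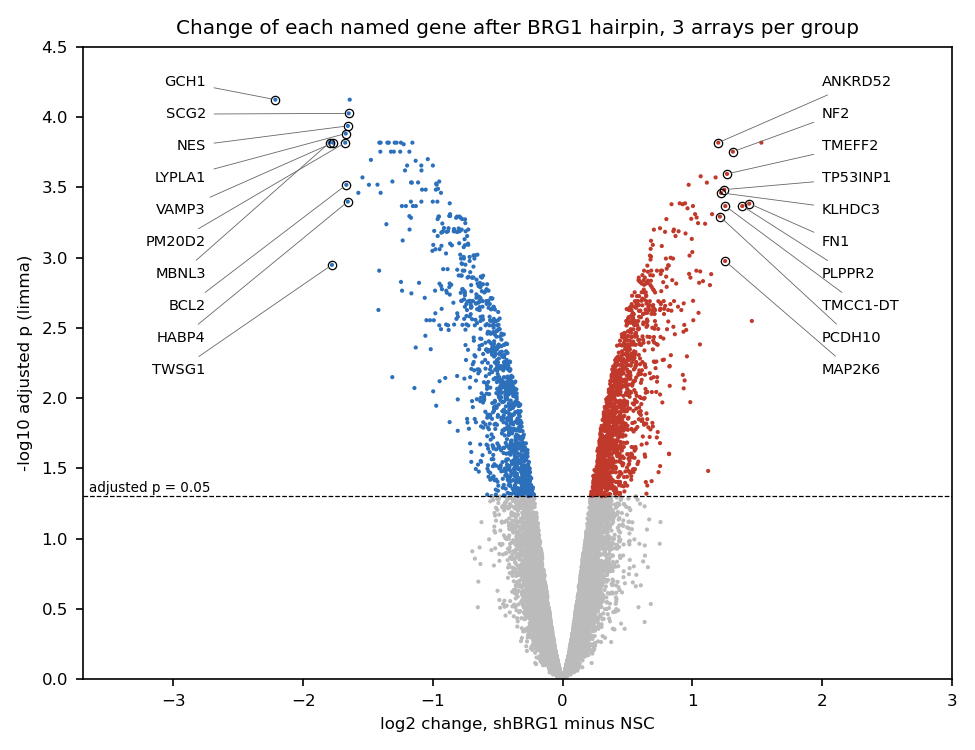
Log2 change of each gene in shBRG1 against NSC (x axis) and -log10 of the limma adjusted p (y axis), with 3 arrays per group, genes past adjusted p 0.05 in red (1455 higher) or blue (1070 lower) and others in grey. Circles mark the 10 genes that rose most and the 10 that fell most under the naming rule, from GCH1 at -2.21 to FN1 at 1.44, and the unlabelled red points beyond FN1 carry LINC symbols, which the rule leaves out as uncharacterised loci.

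Genes of apoptosis and survival that changed were lower, on both sides of the pathway. Among 14 measured anti-apoptotic and survival factors, 0 rose, 4 fell and 10 were not past the threshold, and 1 rose with dim genes left out or with trend and robust options. BCL2 fell most, and the caspase inhibitor XIAP (-0.42, adjusted p = 0.0061), the co-chaperone BAG3 (-0.42) and the apoptosis inhibitor API5 (-0.41) also fell. Among 16 pro-apoptotic factors and caspases, 0 rose and 4 fell, led by APAF1, the scaffold of the apoptosome (1.93-fold lower, -0.95, SE 0.10, adjusted p = 0.0015), and PMAIP1, the BH3-only protein NOXA (-0.74, adjusted p = 0.0021). BNIP3L (-0.30) and BCL2L11, which encodes BIM (-0.41), were the others. Counts adjusted over the list alone were the same, 4 lower in each list. BCL2L1, which encodes BCL-XL, had a change of 0.18 (adjusted p = 0.25). As groups, neither list passed camera (adjusted p = 0.13 for the anti-apoptotic and 0.14 for the pro-apoptotic list, both 0.49 with an estimated correlation). Both lists were lower with an adjusted p of 0.030 after cyclic loess and 0.047 without NSC replicate 2, within ranges of 0.030 to 0.17 and 0.030 to 0.20 over the alternatives. BNIP3L lost its call without any 1 of the shBRG1 arrays or NSC replicate 1 or 2 (range over the alternatives 0.00060 to 0.080), and BCL2L11 without any 1 of the shBRG1 arrays or NSC replicate 1 or 3 and under both other scalings (0.030 to 0.14).

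Of the 13 measured p53 target genes, 3 rose, 2 fell and 8 were not past the threshold (4 and 3 adjusted over the list alone). TP53INP1 rose (1.25, SE 0.09, adjusted p = 3.3e-04), as did the kinase PLK2 (0.78, adjusted p = 0.0020) and TRIAP1 (0.57, adjusted p = 0.012). PLK3 (-0.43) and RRM2B, the p53-inducible ribonucleotide reductase subunit (-0.45), fell. As a group it did not pass camera (adjusted p = 0.51, and 0.72 with an estimated correlation), and its median (-0.02) differed in sign from its mean (0.13) and from the direction of the test. PLK3 lost its call without NSC replicate 2 or shBRG1 replicate 2 or 3 (adjusted p 0.0037 to 0.055 over the alternatives), and RRM2B without any 1 of 5 arrays, NSC replicate 2 excepted (0.010 to 0.10).

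Genes of G2/M and mitosis were lower as a group by camera with its preset correlation (adjusted p = 1.7e-06, list median -0.13), a call lost with a correlation estimated from the 6 arrays (adjusted p = 0.28 with an estimated correlation). Among 32 measured members, 13 fell, 0 rose and 19 were not past the threshold, and the count was the same adjusted over the list alone. The cytokinesis factor ECT2 was 2.45-fold lower (-1.29, SE 0.06, adjusted p = 1.5e-04), from 9.27 ± 0.02 to 7.97 ± 0.04. HMMR (-0.81), the kinesin KIF14 (-0.65) and the proliferation marker MKI67 (-0.50, adjusted p = 0.0024) also fell. The kinesin KIF18A had a change of -0.12 (adjusted p = 0.26).

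DNA replication and G1/S genes went both ways. Of 31 measured members, 8 fell, 5 rose and 18 were not past the threshold, and 11 fell and 6 rose adjusted over the list alone. With dim genes left out, 11 fell and 8 rose. Both E-type cyclins fell, CCNE1 by 0.78 and CCNE2 by 0.74 on the log2 scale (adjusted p = 0.0010 and 7.0e-04), as did the sliding clamp PCNA (-0.53, adjusted p = 0.0039). GINS1 rose (0.43, adjusted p = 0.0067), and so did MCM5 (0.45), MCM7 (0.36), GINS2 (0.39) and GINS3 (0.37), whereas MCM6, a subunit of the same helicase as MCM5 and MCM7, fell by 0.47 on the log2 scale (adjusted p = 0.0079). CCND1, the cyclin of early G1, had a change of -0.05 (SE 0.07, adjusted p = 0.68). Camera gave the list an adjusted p of 0.44 (0.85 with an estimated correlation), and its median (0.03) differed in sign from its mean (-0.07) and its test. GINS2 lost its call without NSC replicate 1 or 2 or shBRG1 replicate 2 or 3 (adjusted p 0.00085 to 0.067 over the alternatives), and GINS3 without these or shBRG1 replicate 1 (0.0013 to 0.065).

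Members of the PI3K/AKT/mTOR list changed in both directions. The insulin receptor INSR was 1.82-fold lower (-0.87, SE 0.08, adjusted p = 7.9e-04), and the insulin-like growth factor receptor IGF1R 1.73-fold lower (-0.79, SE 0.08, adjusted p = 9.5e-04), from 8.70 ± 0.07 to 7.91 ± 0.09. FGFR1 fell as well (-0.64, adjusted p = 0.0015). In all, 5 of 26 measured members of the PI3K/AKT/mTOR list fell, 2 rose and 19 were not past the threshold (5 and 3 adjusted over the list alone), and after cyclic loess 1 rose. The transcription factor FOXO1 (-0.29) and the receptor MET (-0.41) fell, whereas DDIT4 (0.28) and TSC1 (0.33), which encode inhibitors of mTOR complex 1, rose. AKT1 had a change of -0.05 (SE 0.08, adjusted p = 0.72). As a whole the list did not pass camera (adjusted p = 0.25, and 0.48 with an estimated correlation). DDIT4 and TSC1 lost their calls without any 1 of the 6 arrays and after cyclic loess (adjusted p 0.0092 to 0.12 and 0.0067 to 0.11 over the alternatives). FOXO1 lost its call without any 1 of 5 arrays, NSC replicate 1 excepted (0.0053 to 0.080), and MET without NSC replicate 1 or any 1 of the shBRG1 arrays (0.028 to 0.090).

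MYC was dim (3.48 ± 0.16 in NSC), with a change of -0.27 (adjusted p = 0.19). Of 20 measured MYC/MYCN target genes of ribosome biogenesis and metabolism, 3 rose, 2 fell and 15 were not past the threshold (5 and 2 adjusted over the list alone). With dim genes left out 6 rose, and with trend and robust options 8 rose, with 2 lower in both. The spermidine synthase gene SRM rose (0.61, adjusted p = 0.0015), with WDR12 (0.37) and FBL (0.29), and WDR43 (-0.55) and RRS1 (-0.39) fell. The list did not pass camera (adjusted p = 0.20, and 0.49 with an estimated correlation). FBL lost its call without NSC replicate 1 or 2 or shBRG1 replicate 2 or 3 (adjusted p 3.1e-04 to 0.082 over the alternatives).

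Genes of the adrenergic identity of neuroblastoma, the sympathetic neuroblast state, were lower as a group by camera with its preset correlation (adjusted p = 5.3e-04, list median -0.27). That call was lost with an estimated correlation (adjusted p = 0.44 with an estimated correlation). Among 29 measured members, 11 fell, 2 rose and 16 were not past the threshold, and 17 fell and 3 rose adjusted over the list alone. The receptor tyrosine kinase RET fell most (-0.59, SE 0.07, adjusted p = 0.0017), from 10.48 ± 0.01 to 9.89 ± 0.07. The lineage transcription factor PHOX2A (-0.51, adjusted p = 0.0033), the granule protein CHGA (-0.48, adjusted p = 0.0027) and DLK1 (-0.43, adjusted p = 0.0041) fell too. TBX2 (0.59) and LIN28B (0.41) rose.

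Mesenchymal identity genes changed in both directions. Of 23 measured members, 1 rose and 5 fell (2 and 5 adjusted over the list alone). After centring 2 rose and 3 fell, after cyclic loess or with array weights 2 rose and 5 fell, and with trend and robust options or with dim genes left out (7 members) 1 rose and 3 fell. FN1 was the one that rose, whereas the AP-1 subunit FOSL2 (-0.56, adjusted p = 0.0030) and the transcription factor SNAI2 (-0.47, adjusted p = 0.0092) fell. IRF1 (-0.33), the hyaluronan receptor CD44 (-0.28, adjusted p = 0.033) and MAML2 (-0.31) fell too. IRF1 was dim (3.68 ± 0.02 in NSC), so its fall rests on values that may be background. The list did not pass camera (adjusted p = 0.18, and 0.44 with an estimated correlation). CD44 and IRF1 lost their calls without any 1 of 5 arrays, shBRG1 replicate 2 excepted, and with trend and robust options, and CD44 also after centring (adjusted p 0.025 to 0.11 and 0.018 to 0.085 over the alternatives). MAML2 lost its call without any 1 of 5 arrays, NSC replicate 2 excepted, after centring and when its probe sets were averaged (change -0.09; 0.014 to 0.61 over the alternatives).

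Of 18 measured genes of neuronal differentiation, 2 fell and 0 rose. The count was 4 lower and 0 higher after cyclic loess or with dim genes left out, and 5 lower and 2 higher with trend and robust options. SCG2 was 3.13-fold lower, and the synaptic vesicle protein SYP fell by 0.36 on the log2 scale, with an adjusted p of 0.030 that was lost without any 1 of 5 arrays, shBRG1 replicate 2 excepted (0.0041 to 0.086 over the alternatives). SYT1 (-0.19, adjusted p = 0.087) and MAP2 (-0.16, adjusted p = 0.13) were not past the threshold. Of 9 Schwann and glial markers, a list of another cell type of the lineage, 1 fell (3 adjusted over the list alone) and 0 rose. That gene was FOXD3 (-0.24, adjusted p = 0.041), a dim transcript (2.92 ± 0.05 in NSC) whose call was lost without each of the 6 arrays in turn, under both other scalings and with trend and robust options (range 0.038 to 0.11), and 0 markers fell after centring or with trend and robust options. SOX10 (-0.29, adjusted p = 0.053) and S100B (-0.41, adjusted p = 0.072) did not pass. Both lists had a camera adjusted p of 0.18, and 0.44 with an estimated correlation. The neuronal list was lower with an adjusted p of 0.030 after cyclic loess, in a range of 0.030 to 0.31.

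**Figure D2:**
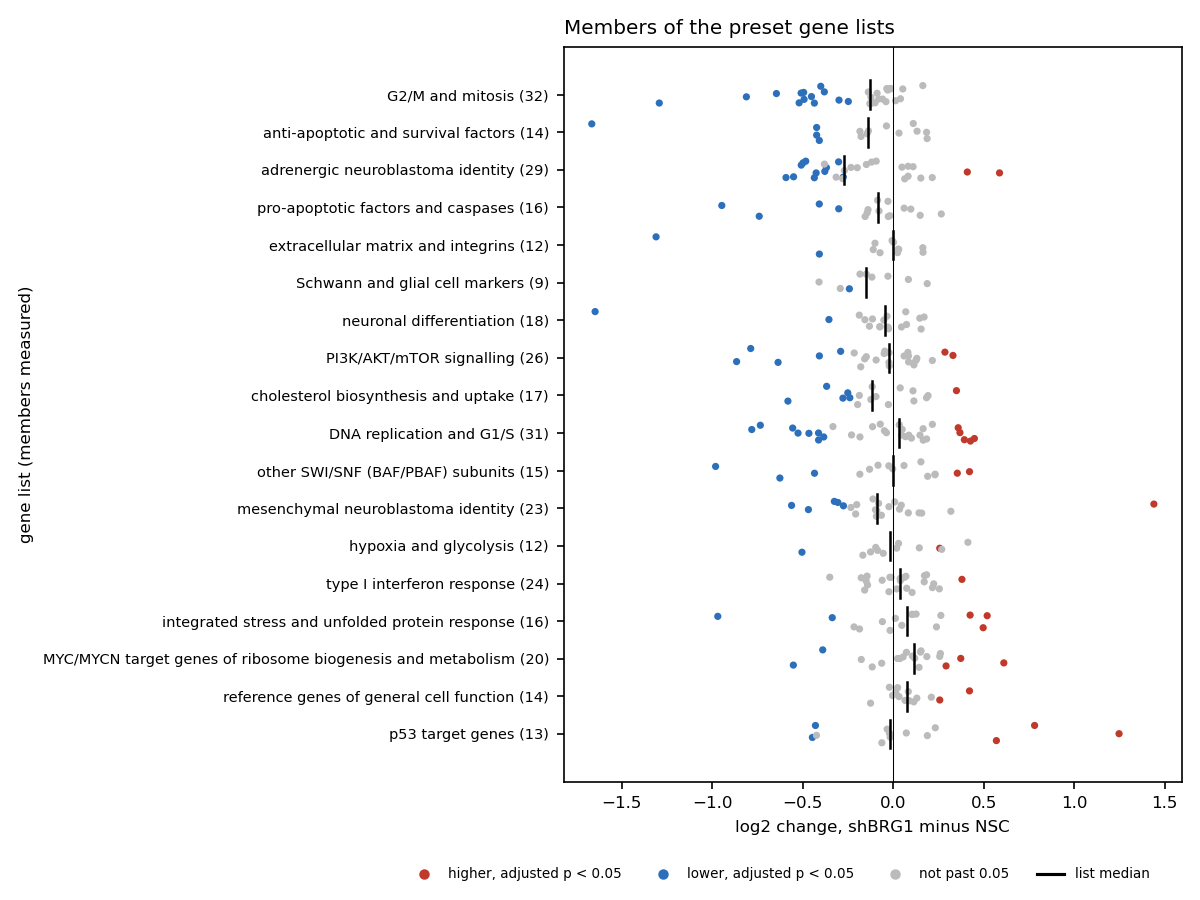
Log2 change in shBRG1 against NSC (x axis) of each measured member of the 18 gene lists (y axis, members measured in parentheses), with red and blue points past adjusted p 0.05, grey points not past it and black bars at list medians. The mitosis list (13 of 32 lower, median -0.13) and the adrenergic list (11 of 29 lower, median -0.27) passed camera with its preset correlation, and both calls were lost with an estimated one (adjusted p = 0.28 and 0.44 with an estimated correlation).

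Among 15 other measured SWI/SNF subunits of 29 listed, 2 rose and 3 fell, with the same count adjusted over the list alone. With dim genes left out, 4 rose and 4 fell. The listed SMARC subunits, ARID2, BRD9, the DPF genes and SS18 were not analysed here, so the counts cover only part of the complex. PHF10, a subunit of the PBAF form, was 1.98-fold lower (-0.98, SE 0.11, adjusted p = 0.0017), and PBRM1, another PBAF subunit, fell by 0.44 on the log2 scale (adjusted p = 0.013). BCL7A fell (-0.63), and BICRA (0.42) and BICRAL (0.35) rose. The list did not pass camera (adjusted p = 0.84, and 0.86 with an estimated correlation). BCL7A lost its call without NSC replicate 1 or 3 or shBRG1 replicate 1 or 3 (adjusted p 0.0048 to 0.085 over the alternatives), BICRAL without NSC replicate 2 or 3 or shBRG1 replicate 1 or 2 (0.0052 to 0.070), and BICRA without shBRG1 replicate 2 (0.0035 to 0.052).

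Of 16 genes of the integrated stress and unfolded protein response, 3 rose and 2 fell (5 and 2 adjusted over the list alone, as with trend and robust options). The stress-induced transcription factor ATF3 was 1.96-fold lower (-0.97, SE 0.07, adjusted p = 3.0e-04) and XBP1 fell (-0.34), whereas SESN2 (0.50), the serine synthesis enzyme PSPH (0.42) and CTH (0.52) rose. The camera adjusted p of this list was 0.60 (0.85 with an estimated correlation). XBP1 lost its call without NSC replicate 1 or 3 or shBRG1 replicate 1 or 3 (0.0013 to 0.075 over the alternatives), and CTH without NSC replicate 1 or 2 or shBRG1 replicate 2 or 3 (0.018 to 0.10).

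Of 17 cholesterol genes, 5 fell and 1 rose (6 and 2 adjusted over the list alone), and 3 fell after centring. The sterol carrier STARD4 fell by 0.58 (adjusted p = 0.0020) and IDI1 by 0.37 on the log2 scale, followed by HMGCS1 (-0.28), NSDHL (-0.25) and SQLE (-0.24), and PMVK rose (0.35). The list had a camera adjusted p of 0.16 (0.44 with an estimated correlation), and passed in 3 alternatives, with 0.030 after cyclic loess, 0.043 with dim genes left out and 0.030 with trend and robust options in a range of 0.030 to 0.22. NSDHL and SQLE lost their calls without any 1 of the 6 arrays and after centring (0.0041 to 0.12 and 7.8e-04 to 0.14), HMGCS1 without any 1 of 5 arrays, NSC replicate 3 excepted (7.7e-04 to 0.086), and PMVK without NSC replicate 2 or 3 or shBRG1 replicate 3 (0.0023 to 0.058).

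Of 12 hypoxia and glycolysis genes, VEGFA fell (-0.51, adjusted p = 0.0045) and EGLN3 rose (0.26, adjusted p = 0.049), with 3 rising and 1 falling adjusted over the list alone. With trend and robust options 2 rose, and after cyclic loess or with array weights 0. The remaining 10 were not past the threshold. The list had a camera adjusted p of 0.86, also with an estimated correlation, and a mean of 0.01 against a median and a test below 0. EGLN3 lost its call without each of the 6 arrays in turn, under both other scalings, with trend and robust options and with array weights (range 0.048 to 0.13).

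Of 12 measured genes of the extracellular matrix list, in which integrins were not analysed here, 2 fell and 0 rose, both inhibitors of metalloproteinases and both also past adjusted over the list alone. TIMP3 was 2.48-fold lower (-1.31, SE 0.09, adjusted p = 2.9e-04), and TIMP2 1.33-fold lower (-0.41, adjusted p = 0.0088). Together the 12 genes did not pass camera (adjusted p = 0.26, and 0.49 with an estimated correlation). Of 24 type I interferon genes, which can respond to a hairpin vector, 1 rose and 0 fell, also adjusted over the list alone. With trend and robust options 2 rose, and with dim genes left out (4 members) 1 rose and 1 fell. The gene that rose in the main fit was IFIT2, a dim transcript (2.95 ± 0.10 in NSC). Its change was 0.38 (adjusted p = 0.018, lost without NSC replicate 1 or 2 or shBRG1 replicate 1 or 3, range 0.013 to 0.064). ISG15 had a change of -0.35 (adjusted p = 0.095). The interferon list had a camera adjusted p of 0.86, also with an estimated correlation. Of 14 reference genes of general cell function, GPI (0.42, adjusted p = 0.0042) and VCP (0.26, adjusted p = 0.038) rose and 0 fell, with the same count adjusted over the list alone and 1 higher after cyclic loess. The reference list did not pass camera (adjusted p = 0.18, and 0.71 with an estimated correlation). VCP lost its call without each of the 6 arrays in turn and after cyclic loess (range 3.5e-04 to 0.12).

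Across the 18 lists, 5 had an unadjusted camera p under 0.05 with the preset correlation and 2 passed after adjustment, and 0 passed with an estimated correlation. By fry, which tests whether the genes of a list move on balance one way and does not compare it with other genes, 13 lists passed. By the mixed form of fry, which asks for change in either direction, 18 lists passed.

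**Figure D3:**
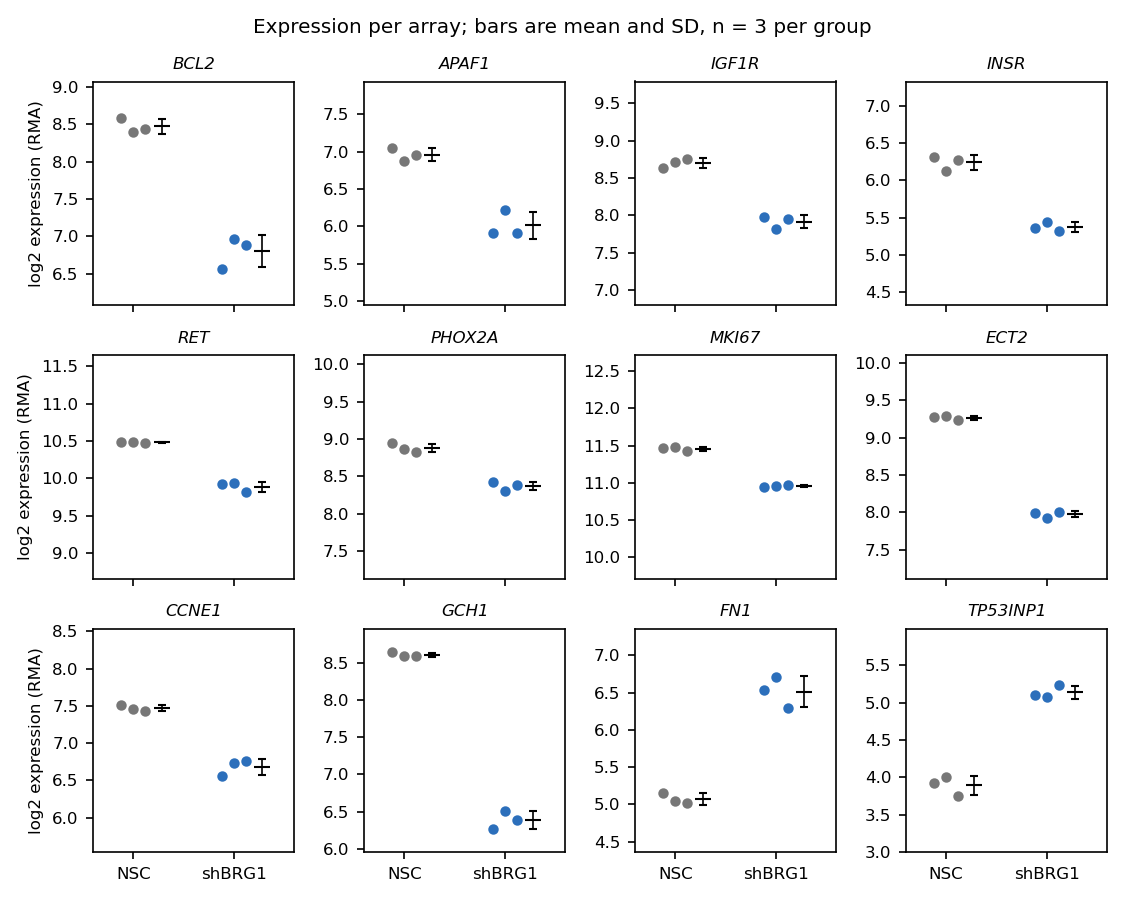
Log2 expression (y axis) of 12 named genes on each of the 3 NSC and 3 shBRG1 arrays (x axis), with points for single arrays and bars for mean and SD. The shBRG1 values lie outside the NSC range in each panel, below it for 10 genes such as BCL2 (8.47 to 6.81) and above it for FN1 (5.07 to 6.51) and TP53INP1 (3.89 to 5.14).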

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

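The tests of this part were chosen before the values were seen, except the count of other splits for genes, which was seen first. Among the 36471 probe sets without a gene symbol, which the comparisons of named genes leave out, 1124 passed when every probe set was tested with limma, 630 higher and 494 lower in shBRG1. This is a signal in data that the named comparisons do not use. It amounts to 3.08% of these probe sets, against 8.31% of those with a symbol, and their median level was lower (3.38 against 5.02). Probe sets 16889730 (2.94, adjusted p = 0.0049) and 16771558 (1.98, adjusted p = 0.027) rose, and 16854540 (-2.62, adjusted p = 0.0011) and 17090320 (-2.11, adjusted p = 8.5e-04) fell, all picked after their values were seen.

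The real grouping of the 6 arrays gave 2525 genes, and the highest of the other splits into 3 and 3 gave 0, with 1 of 10 splits as large. For the lists the real grouping gave 2 and the highest other split 1, again with 1 of 10 as large. With 10 splits the share is never under 0.1, so the splits are too few for a share under 0.05.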

How the results depend on the processing

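The settings were planned, except those of the run on chromosome 14. Centring arrays on their medians (2352 genes), cyclic loess (2541), leaving out dim genes (3201), averaging probe sets (2497), trend and robust options (3306) and array weights (2565) kept the count of genes within 1.5 times of 2525. Testing every probe set called 2440 probe sets, which is not a count of genes. Of these, 1316 carried a symbol, or 8.31% of the named probe sets, against 17.0% of genes in the main fit. The count was 1086 (563 higher, 523 lower) at an adjusted p of 0.01 and 103 (33 higher, 70 lower) with a fold of at least 2, both stricter by construction. Without 1 array it ran from 1604 to 1840, higher genes from 840 to 1055, lower genes from 694 to 859, and lists from 2 to 4. Replicate numbers are shared by the groups, but deviations of same-numbered samples had correlations of -0.04, -0.14 and -0.03 and 0 samples correlated best with their own number, so the numbers do not pair them. With a replicate block the count was 1608, 870 of them higher, and 2 lists passed, while of the 5 families by symbol stem INTS did not (adjusted p = 0.071). Lists past the threshold numbered 6 after cyclic loess, 0 with an estimated correlation and 13 by fry, and the cause was not tested. The mitosis and adrenergic lists passed in all 13 other settings of the data or fit (adjusted p 3.0e-09 to 1.7e-05 and 2.5e-05 to 0.0016). Without 1 array the direction of the test reversed in 2 uncalled lists, with medians from -0.0014 to 0.063 (interferon) and from -0.050 to 0.022 (hypoxia). Medians also crossed 0 in the uncalled lists of SWI/SNF subunits (-0.029 to 0.034), DNA replication (-0.035 to 0.037), p53 targets (-0.0042 to 0.072) and extracellular matrix (-0.072 to 0.0067). Of 1597 pairs of a named gene and a setting, 1393 kept direction and side of the threshold, 185 lost the call, 19 gained one and 0 reversed. Of the 103 named genes past the threshold, 72 kept the call in each setting they were tested in, the block aside. The planned checks of SMARCA4 were not run. Signal over background was not used here, so it was not tested whether changes of dim genes such as MYC, MET, FOXD3 and TP53INP1 are understated.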

Other observations

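The tests in this part were chosen after the result was seen, except the leave-one-out and gene order tests of the run on chromosome 14, the brightness test of the mitosis list and the count of splits for lists. Families of genes that share a symbol stem, 135 of them with at least 12 genes, were set against all other genes with camera at its preset correlation. Of 491 ZNF genes, the zinc finger family, 74 rose and 15 fell (adjusted p = 0.0015, and 0.85 with an estimated correlation, median 0.13), and of 21 KDM genes, most of them lysine demethylases, 9 rose and 0 fell (adjusted p = 0.0071, and 0.85 with an estimated correlation, median 0.27). KDM6B was 2.09-fold and KDM7A 2.00-fold higher. Of 26 MRPS genes, which encode mitochondrial ribosomal proteins, 8 rose and 1 fell (adjusted p = 0.023, and 0.85 with an estimated correlation), and of 13 INTS genes of the Integrator complex 6 rose and 1 fell (adjusted p = 0.048, and 0.85 with an estimated correlation). Of 19 PCDHB genes, 5 rose and 0 fell (adjusted p = 0.030, and 0.85 with an estimated correlation), with PCDHB6 2.14-fold and PCDHB2 1.74-fold higher, and near-identical copies in this cluster can share probes. The direction was upward under both other scalings for each of these 5 families. After cyclic loess the adjusted p was 0.013 for ZNF, 0.020 for KDM, 0.023 for PCDHB, 0.13 for MRPS and 0.18 for INTS. Without shBRG1 replicate 2 it was 0.025 for ZNF, 0.058 for KDM, 0.15 for PCDHB, 0.083 for MRPS and 0.088 for INTS, and without NSC replicate 2 it was 0.086 for PCDHB and MRPS and 0.10 for INTS. INTS also missed the threshold without NSC replicate 1 (0.13) or shBRG1 replicate 1 (0.059) or 3 (0.055) and after centring (0.053), and with array weights PCDHB and INTS did (both 0.053).

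Transcripts of the imprinted domain on chromosome 14q32, from DLK1 to MEG9, were lower together. Of 56 measured genes, 52 of them microRNA genes, 27 fell and 0 rose, and 52 had a change below 0 (median -0.42). The domain was chosen after its values were seen. The long transcripts in it, DLK1 (-0.43), MEG3 (-0.72, and -1.10 when its probe sets were averaged), RTL1 (-0.50) and MEG9 (-0.40), were all past the threshold, although RTL1 lost its call without shBRG1 replicate 2 or 3 (adjusted p 0.0016 to 0.057 over the alternatives) and MEG9 without shBRG1 replicate 1 or when its probe sets were averaged (change -0.22; 0.0034 to 0.11 over the alternatives). Of the 10 nearest measured neighbours, 5 on each side, 8 were not past the threshold, 0 rose and 2 fell, both on the DLK1 side. These were BEGAIN (-1.42, adjusted p = 0.0024) and YY1 (-0.28, adjusted p = 0.044), and YY1 lost its call without any 1 of 5 arrays, NSC replicate 2 excepted, and after centring (0.012 to 0.13).

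The 1020 microRNA genes elsewhere had a median change of -0.030 (95% interval -0.042 to -0.020) against -0.42 for those of the domain. They were also dimmer, with a median level of 2.95 against 4.06. Among draws of microRNA genes elsewhere matched for level, the share with a median as low was 1e-04, the smallest that 10000 draws can give. The domain was chosen for its low values and the draws treat genes as independent, so this share does not measure chance. The median change elsewhere was -0.030, so a shift common to all microRNA probe sets does not account for the low values of the domain. Nor does a single array, since the weakest median without 1 array was -0.41. The lowest window of 15 neighbouring genes had a mean t of -5.78, against -5.14 for the lowest in 1000 random gene orders (share 0.001, the smallest they can give). Random orders treat genes as independent, so this speaks only against random placement. Genes read from a shared host RNA would not be separate observations. Lower transcription of the whole domain stays open, because the 4 of 4 long transcripts past the threshold belong to a domain chosen for its low values. The probes read precursor or host RNA, so mature microRNAs were not measured.

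Members of the mitosis list differed in their change, and 46.9% of them (15 of 32) had a 95% interval that leaves out the list median of -0.13, 12 below it and 3 above. ECT2 had a change of -1.29 and CCNB1 of -0.49, whereas CDK1 (-0.03, adjusted p = 0.80) and PLK1 (-0.04, adjusted p = 0.78) were not past the threshold. A lower share of mitotic cells could lie behind the falls and stays open, since members with different levels outside mitosis need not fall equally. Compression of bright probe sets would make brighter members fall less, and no such trend was seen across members. The correlation between level and change was near 0 (Spearman's rho -0.036, permutation p = 0.85, and Pearson's r -0.038, permutation p = 0.84). A weak trend cannot be excluded with 32 members, and genes are not independent replicates, so the test does not decide on compression.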
